A study of Mus musculus with 2 samples.

How the data were processed

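The data are 2 microRNA-seq libraries of mouse midbrain at embryonic day 13.5, made from RNA under 30 nt, 1 library per biological replicate. The deposited values are raw read counts per gene, 1 table per sample, on assembly mm10 with genome annotation M4, per the file headers and the notes deposited with each sample. The aligner, its version, the adapter trimming and the read filters are not given in the sources used here. Each table has 3 columns of counts and no header line. The first count column equals the sum of the other columns in 3946 of 3946 rows over both tables, and from this and the strand of the genes the columns were read as counts without regard to strand, counts on the strand of the gene, and counts on the opposite strand. This reading is an inference from the values. The summary rows for unmapped, multimapping, unassigned and ambiguous reads name no gene and stayed out of library sizes and tests. Unmapped reads were 16.1% of replicate 1 and 15.7% of replicate 2, and multimapping reads 34.4% and 37.7%. Reads not assigned to a gene in the same-strand column were 3.79% and 3.80%, and the ambiguous count was 0 in both.

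Reads that map to several places are in no locus count, which lowers the counts of microRNAs made from identical copies, and the tables do not say which loci those reads came from. Counts are per hairpin, so mature arms were not told apart. Replicate 1 held 5093743 same-strand counts and replicate 2 held 2935841. A floor of 3 counts corresponds to 0.589 and 1.02 CPM.

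Gene names and coordinates came from GENCODE M21, whose coordinates are on the same assembly. Of 1973 gene IDs, 1894 matched by ID without its version, and 1815 had the same version. Coordinates are printed only for loci with the same ID version. The later annotation has 313 microRNA genes without a row in the tables, and these were not analysed here as loci of their own. A locus was called uncertain where its hairpin shares an exact run of 20 nt or more with another annotated microRNA hairpin, which holds for 929 of the 1894 loci with a sequence.

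CPM was computed here from same-strand counts over all gene rows. Loci with at least 10 counts over both replicates (466) entered the tests. With 1 group, edgeR 4.0.16 could fit no contrast and served for TMM factors and the common biological coefficient of variation in an intercept-only design, with 100 bootstrap draws of loci. The libraries were compared per locus by a two-sided exact conditional binomial test given TMM-scaled library sizes, with Benjamini-Hochberg adjustment at 0.05 (scipy 1.17.1, R 4.3.3, Python 3.11.15). Ratios use a pseudocount of 0.5 CPM. The correlation interval came from 1000 bootstrap draws. List shares have 95% exact Clopper-Pearson intervals. A list's median level was placed among 10000 random lists drawn from all loci, with ties given a weight of 0.5, and its median ratio among 10000 random lists matched on 10 tiers of expression. The tie weight was set after a first run, in which ties at 0 counts had been scored as not below, and the number of lists at or above the 95th percentile was 16 with either scoring.

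The test was tried on simulated counts for the 466 loci of replicate 1 against replicate 2. In counts with no spread between replicates beyond counting error, it called 64% of loci changed 1.5-fold, 78% of loci changed 2-fold and 1.88% of unchanged loci. In a separate simulation with a coefficient of 0.2 between replicates and no changed locus, it called 48.3% of loci, so a call does not separate a locus from ordinary spread between samples. That coefficient was estimated as 0.201.

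The 17 lists, with 258 members of which 228 have a row, and the rule for named loci were fixed before the data were examined. The rule names the 20 loci of highest mean CPM, the 4 highest members of each list, every Mir9 and Mir124 locus, and the 5 loci highest in each replicate by fold among those past the test with a mean of at least 100 CPM. It gave 81 loci. Alternatives were DESeq2 1.42.0 size factors, total counts only, other count minimums, unstranded counts, thinning of the deeper library, another pseudocount and each replicate left out. Another 5 alternatives were chosen after seeing the data: a required fold of at least 1.5, a denominator without Mir99a, multimapping reads in the denominator, opposite-strand counts added to the list members they overlap, and total counts only for the test of list sums.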

Results

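MicroRNA sequencing measured the small RNA (under 30 nt) of the midbrain, the middle vesicle of the embryonic brain, in mouse embryos of the B6NCrl strain at embryonic day 13.5. The tissue was pooled from male and female embryos. The series holds 1 group of 2 biological replicates, each a separate tissue sample with its own library. Both samples carry the same donor record, and how far the embryos of the 2 pools were independent is not given in the sources used here. No second tissue, age or treatment is part of the series, so the design implies no comparison between conditions. The data answer which microRNAs the midbrain held at this age, how the counts were spread over them, and how closely the replicates matched.

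Replicate 1 held 5093743 reads assigned to a gene on its own strand and replicate 2 held 2935841, a depth ratio of 1.74. These were 45.7% and 42.8% of all reads in the tables. A count of 0 allows a level of up to 0.589 CPM (counts scaled to the library total) in replicate 1 and 1.02 CPM in replicate 2, from 3 counts. Reads carried no molecular identifiers in the tables, so these limits and the binomial intervals of shares cover counting error only. Values are given as mean CPM of same-strand counts ± SD over the 2 replicates (n = 2) unless stated otherwise. An SD of 2 values that happen to lie close can fall below counting error, as for Mir124a-1, with 12 and 7 counts. Counts are per hairpin locus, and both arms of a hairpin fall in 1 count.

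Mir99a, of the miR-99/100 family, held the most counts, and Mir100, Mir99b, Mirlet7g and Mirlet7i were also in the top 10. This ranking leaves out multimapping reads, which are in no locus count. Mir99a alone took 20.9% ± 0.577 of all counts (SD, n = 2), at 209489 ± 5772 CPM. Mir335 followed at 56559 ± 456 CPM, Mir100 at 52256 ± 2409 CPM, Mirlet7g at 45544 ± 2135 CPM and Mir17, of the proliferation-associated miR-17/92 cluster, at 41984 ± 6815 CPM. Mir130a stood at 35718 ± 1411 CPM, Mir99b at 30915 ± 2025 CPM, Mirlet7i at 24103 ± 4897 CPM, Mir487b at 21992 ± 1093 CPM and Mir93 at 20765 ± 1745 CPM. The 10 most abundant loci held 53.9% ± 0.854 of the counts, the top 20 held 69.3% ± 0.971 and the top 50 held 86.8% ± 0.362. With multimapping reads added to the denominator, an alternative chosen after seeing the data, the share of the top 10 was 29.7%.

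Places 11 to 20 went to Mir30e (19928 ± 2105 CPM), Mir26b (19031 ± 2720 CPM), Mir149 (18860 ± 507 CPM), Mir126a (18713 ± 3474 CPM), Mir181c (17644 ± 364 CPM), Mir20a (16879 ± 2464 CPM), Mir106b (12061 ± 529 CPM), Mir135b (11089 ± 478 CPM), Mir30a (9599 ± 610 CPM) and Mir322 (9564 ± 1020 CPM). The order of neighbours closer than their SDs is not resolved by 2 replicates.

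**Figure D1:**
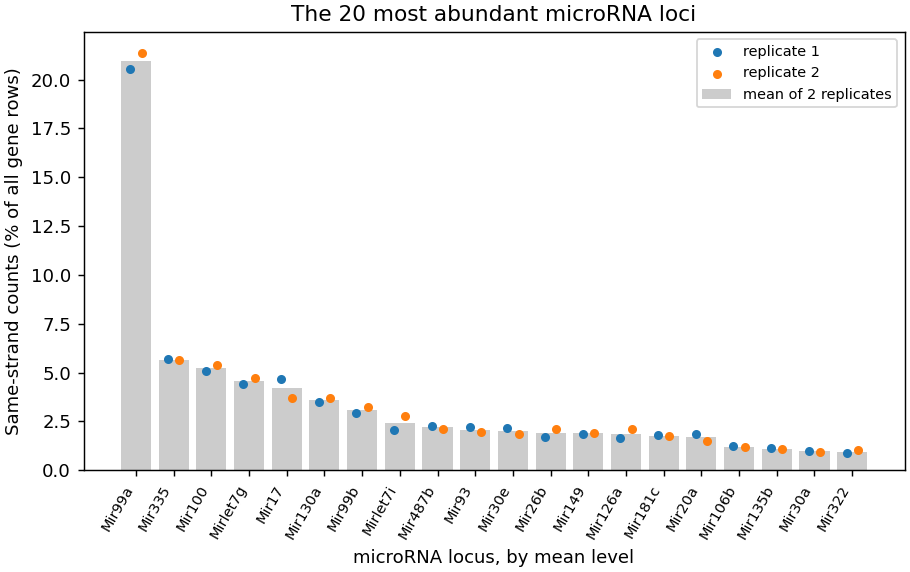
The 20 most abundant microRNA loci in the embryonic midbrain, as the percent of same-strand counts of all gene rows (vertical axis) per locus (horizontal axis); bars are means of 2 replicates and points are the replicates. Mir99a holds 20.9% and no other locus passes 5.66%.

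Most of the leading loci lie within host transcripts. On mm10, Mir99a (ENSMUSG00000065530.1) lies on chromosome 16 from 77598936 to 77599000, in an intron of the long noncoding transcript Mir99ahg. Mir335 lies on chromosome 6 from 30741299 to 30741396, in an intron of the imprinted gene Mest. Mir100 lies on chromosome 9 from 41531425 to 41531504, in an intron of 3110039I08Rik, and Mirlet7g on the same chromosome from 106178840 to 106178927, in an intron of Wdr82. Mir17 lies on chromosome 14 from 115043671 to 115043754 and overlaps an exon of Mir17hg. Mir126a lies on chromosome 2 from 26591357 to 26591429 and overlaps an exon of the endothelial gene Egfl7. Mir130a, on chromosome 2 from 84741115 to 84741178, has no annotated host on its strand.

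Expression was spread over a minority of the annotated loci. Of 1973 loci in the tables, 449 reached 1 CPM in both replicates, 308 reached 10 CPM, 202 reached 100 CPM and 88 reached 1000 CPM. No read was counted at 1254 loci in either library, which at this depth sets a limit on their level and does not show that they are absent.

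The let-7, miR-125 and miR-99/100 list, whose let-7 members are timing regulators that rise as progenitors mature, held the most counts of the 17 lists, 38.2% ± 1.80. With Mir99a left out, an alternative chosen after seeing the data, its share was 21.8%. All 16 of its loci in the tables exceeded 100 CPM in both replicates. Mir99a, Mir100, Mirlet7g and Mir99b led the list. Between the libraries, 3 loci were higher in replicate 1, 11 were higher in replicate 2 and 2 did not pass the test, with the same counts adjusted over the list alone.

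The neuronal list held 12.9% ± 0.362 of the counts, and 27 of its 42 loci exceeded 100 CPM in both replicates. Its 4 leading members were Mir335, Mir149, Mir135b and Mir92b, the last at 9214 ± 1094 CPM. Mir335 alone held 5.66% of all counts, so the share of the list is no measure of how many neurons the tissue held. Of 40 tested members, 15 were higher in replicate 1, 7 were higher in replicate 2 and 18 did not pass, also when adjusted over the list alone. With total counts only the split was 19 and 5, and with thinning 13 and 7 of 39. Loci of miR-9 and miR-124, the classical microRNAs of neural progenitors and neurons, had low counts. Mir9-3 stood at 377 ± 33.8 CPM, Mir9-2 at 2.08 ± 0.437 CPM, Mir124a-2 at 9.31 ± 0.160 CPM, Mir124a-1 at 2.37 ± 0.0201 CPM and Mir124a-3 at 1.64 ± 0.0937 CPM (3.37 CPM with unstranded counts). Each of these 5 loci shares an exact run of at least 20 nt with another annotated microRNA locus, and reads that map to several places are not in any locus count, so these values are not the level of the mature microRNA.

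MicroRNAs of the miR-17/92 cluster and its paralogs, linked to progenitor proliferation, held 10.5% ± 1.30 of the counts. Mir17, Mir93, Mir20a and Mir106b led, and 11 of the 15 loci exceeded 100 CPM in both replicates. Replicate 1 was higher at 9 loci, replicate 2 at 1, and 5 did not pass, with the same counts adjusted over the list alone.

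The imprinted Dlk1-Dio3 clusters, expressed from the maternal chromosome, held 7.99% ± 0.616 of the counts. With opposite-strand counts added to the list members they overlap, an alternative chosen after seeing the data, the share was 9.15%. Among members with a row, Mir487b led, followed by Mir369 (8590 ± 297 CPM), Mir382 (6584 ± 664 CPM) and Mir127 (6519 ± 763 CPM), and 34 of 51 loci exceeded 100 CPM in both replicates. Mir409, a member without a row, would stand at 7154 ± 899 CPM if the opposite-strand counts at its place were its own. Mir487b shares a run of at least 20 nt with another locus and is uncertain. Of 47 tested loci, 25 were higher in replicate 1 and 2 in replicate 2, while 20 did not pass (26 and 2 adjusted over the list alone). With total counts only these were 32 and 1, and with thinning 23 and 1 of 46. The median log2 ratio of replicate 1 to replicate 2 was 0.14, at the 99.95th percentile of 10000 random lists of the same size matched on expression. In the other direction, the liver, pancreas and pituitary list lay at 0.67, the choroid plexus list at 2.93 and the mural list at 4.89, and the other 13 lists lay between 6.90 and 93.2. The percentile describes these libraries only, since the Dlk1-Dio3 loci lie in 1 region and are not independent of each other, unlike the loci of the random lists.

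Markers of other cell types were present at lower shares. Mir126a, the endothelial locus, held 1.63% of counts in replicate 1 and 2.12% in replicate 2. The mural and mesenchymal list held 0.897% and 1.08%, led by Mir143 (5809 ± 1156 CPM), Mir140 (3667 ± 120 CPM), Mir214 (242 ± 19.2 CPM) and Mir199b (104 ± 5.28 CPM). Of its 6 tested loci, 4 were higher in replicate 2 (3 with thinning) and 2 did not pass. The glial list held 1.04% and 1.13%, with Mir21a at 4417 ± 359 CPM, Mir23a at 3732 ± 772 CPM, Mir219a-2 at 1704 ± 181 CPM and Mir219a-1 at 730 ± 10.6 CPM. Of 7 tested glial loci, 1 was higher in replicate 1, 3 were higher in replicate 2 and 3 did not pass, and the call of Mir24-2, higher in replicate 2, ended with thinning, with no filter and with total counts only. Mir21a and Mir23a are made by many cell types, whereas miR-219 is a microRNA of oligodendrocyte differentiation. Mir199b, Mir23a, Mir219a-1 and Mir219a-2 share runs with another locus and are uncertain.

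Blood and muscle lists were near the bottom. The leukocyte list held 0.0360% and 0.0405%, with Mir223 at 172 ± 39.6 CPM, Mir155 at 136 ± 16.3 CPM, Mir146 at 47.6 ± 11.2 CPM and Mir150 at 26.1 ± 2.23 CPM. Mir146 shares a run with another locus and is uncertain. Of the 5 tested leukocyte loci, Mir223 and Mir146 were higher in replicate 2 and 3 did not pass, while Mir155 passed with total counts only (0.25, higher in replicate 1). Adding opposite-strand counts to the list members they overlap, chosen after seeing the data, gave the leukocyte list a mean of 0.0625% in place of 0.0383%. Erythroid loci held 0.00934% and 0.00869%, with Mir451a at 46.7 ± 10.1 CPM, Mir144 at 31.0 ± 4.37 CPM and Mir486 at 12.5 ± 1.06 CPM. Mir451a was higher in replicate 1 over all loci tested but not with unstranded counts, and none of the 3 erythroid loci passed when adjusted over the list alone. Muscle loci held 0.00638% and 0.00654%, led by Mir208b at 40.1 ± 1.14 CPM, Mir206 at 12.6 ± 2.94 CPM, Mir208a at 5.15 ± 0.902 CPM and Mir499 at 3.39 ± 1.47 CPM, and none of 5 tested loci passed, whereas with replicate 1 thinned to equal depth Mir499 passed (log2 ratio -2.12 in place of -0.84).

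Regional and epithelial lists were also low. MicroRNAs of the Hox clusters, genes that pattern the hindbrain and spinal cord, held 0.0637% and 0.0723%. Mir10a stood at 425 ± 61.3 CPM, Mir10b at 217 ± 3.62 CPM, Mir196b at 21.7 ± 0.374 CPM and Mir615 at 15.2 ± 3.20 CPM, and of 4 tested Hox loci Mir10a passed, higher in replicate 2, with Mir10b passing too (log2 ratio -0.20) when replicate 1 was thinned to equal depth. The epithelial and sensory list held 0.289% and 0.241%, with Mir183 at 984 ± 67.3 CPM, Mir182 at 697 ± 276 CPM, Mir203 at 573 ± 28.8 CPM and Mir96 at 316 ± 34.4 CPM. Of its 10 tested loci, 2 were higher in replicate 1, 2 in replicate 2 and 6 did not pass, but with thinning 1 was higher in each replicate and 8 did not pass, as the calls of Mir96 and Mir429 ended. The miR-290 and miR-302 clusters of pluripotent cells held 0.195% and 0.190%, with Mir302a at 761 ± 45.3 CPM, Mir302d at 631 ± 4.04 CPM, Mir302b at 446 ± 0.740 CPM and Mir302c at 55.4 ± 2.05 CPM, and none of 8 tested loci passed, whereas with total counts only Mir302a passed (log2 ratio 0.12). Mir302a and Mir302b share runs with another locus and are uncertain. The Sfmbt2 intron cluster, known from placenta, held 0.527% and 0.607%, with Mir467c at 1831 ± 260 CPM, Mir467d at 1504 ± 255 CPM, Mir467e at 1385 ± 35.9 CPM and Mir669o at 489 ± 9.50 CPM. Of 8 tested Sfmbt2 loci, 4 were higher in replicate 2 (5 adjusted over the list alone) and the others did not pass. This count was 3 with DESeq2 size factors, with no filter and with thinning, and 2 (Mir467c and Mir467d) with total counts only. All 4 named Sfmbt2 loci share runs with near-identical copies and are uncertain. Mirtrons, hairpins released by splicing, held 0.0329% and 0.0277%, with Mir877 at 115 ± 21.2 CPM, Mir702 at 54.3 ± 16.2 CPM, Mir1981 at 53.3 ± 0.704 CPM and Mir3102 at 42.5 ± 2.96 CPM, and 2 of 6 tested loci were higher in replicate 1 (1 with thinning).

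Some choroid plexus and endocrine microRNAs differed between the libraries. The choroid plexus and pigment epithelium list held 0.0752% in replicate 1 (95% exact Clopper-Pearson interval 0.0728 to 0.0776) and 0.104% in replicate 2, whose interval lay above that of replicate 1. Mir204 (877 ± 200 CPM) was higher in replicate 2 and Mir211 (18.1 ± 2.83 CPM) did not pass. The liver, pancreas and pituitary list held 0.120% (0.117 to 0.123) and 0.213% (0.208 to 0.218). Mir375 (944 ± 595 CPM) and Mir122 (99.1 ± 56.9 CPM) were higher in replicate 2, whereas Mir217 (270 ± 14.9 CPM), Mir216b (112 ± 4.12 CPM) and 3 further loci did not pass. Over all 17 lists, the summed counts of 14 differed between the libraries by the exact conditional binomial test given TMM-scaled library sizes, after Benjamini-Hochberg adjustment, and the pluripotency, erythroid and muscle lists did not pass. With total counts only, which compares the shares themselves and was chosen after seeing the data, 14 lists also passed. The neuronal list has no direction, since its log2 ratio of replicate 1 to replicate 2 was -0.0097 with TMM scaling and 0.057 as a share, past the test both ways.

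**Figure D2:**
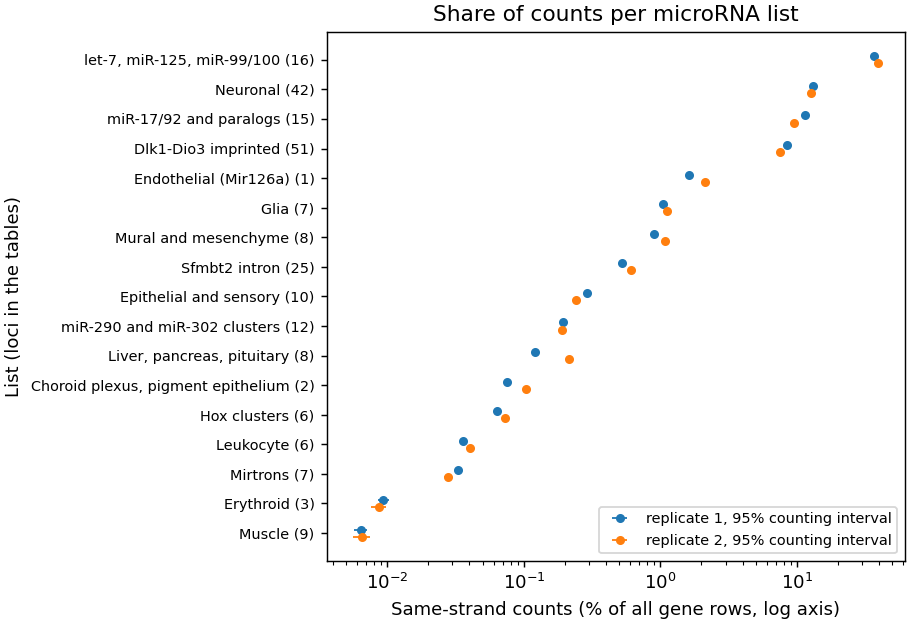
Share of same-strand counts of all gene rows (percent, log axis) held by each of 17 microRNA lists, with the number of loci in the tables in parentheses; points are the 2 replicates and bars their 95% exact Clopper-Pearson intervals, which cover counting error only. The shares run from 38.2% for the let-7, miR-125 and miR-99/100 list down to 0.00646% for muscle.

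Median levels of 16 of the 17 lists lay at or above the 95th percentile of random lists drawn from all loci of the tables, and the Sfmbt2 list lay at 93.8. Without replicate 1 the Sfmbt2 list lay at 48.5, and without replicate 2 at 96.8. Most loci of the tables have no count, and among loci with at least 10 counts 6 lists lay at or above the 95th percentile. These were the let-7, neuronal, miR-17/92, Dlk1-Dio3, endothelial and glial lists.

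The replicates ranked the loci alike. Across 466 loci with at least 10 counts, Spearman's rho was 0.983 (bootstrap interval 0.975 to 0.989) and Pearson's r of log2(CPM + 0.5) was 0.992. These are correlations across loci, which are not independent replicates. Of 205 loci at a mean of 100 CPM or more, 192 (93.7%) lay within 1.5-fold of each other, and the SD of their log2 ratio was 0.31. The common biological coefficient of variation was 0.157 (bootstrap interval 0.137 to 0.180). The draws were of loci, so the interval does not cover the uncertainty of a spread taken from 1 pair of libraries.

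The counts of the libraries did not agree within sampling noise, with a chi-square of 103 per degree of freedom. The exact conditional binomial test, adjusted by Benjamini-Hochberg, called 178 of 466 loci, 88 higher in replicate 1 and 90 higher in replicate 2. The share higher in replicate 1 was 49.4% with TMM scaling and 61.9% with total counts only. Of the called loci, 15 differed at least 2-fold, and 3 of them had a mean of 100 CPM or more, Mir375, Mir449a and Mir1298, all higher in replicate 2. With DESeq2 size factors or with no filter, Mir7b joined them, higher in replicate 1. With total counts only, 4 loci at 100 CPM or more differed at least 2-fold, Mir375 and Mir449a higher in replicate 2, and Mir7b and Mir181b-2 higher in replicate 1. Among other named loci, the calls of Mir106b, Mir96 and Mir877 ended with thinning and those of Mir203 and Mir467e with total counts only, and Mir135b, Mir369, Mir183 and Mir9-3 passed with total counts only and with no filter, Mir135b also with DESeq2 size factors. The test compares these 2 libraries and no conditions, and it takes in no spread between animals. In simulated counts with a coefficient of 0.2 between replicates and no changed locus, it called 48.3% of loci, against 38.2% of the loci here. The simulated coefficient is larger than the 0.157 estimated here, so the 2 percentages are not a like comparison.

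Mir375, a microRNA of endocrine cells, was 2.73-fold higher in replicate 2 (log2 ratio of replicate 1 to replicate 2 -1.45). Mir449a, known from multiciliated cells and hosted by an intron of Cdc20b, stood at 1512 ± 925 CPM and was 2.64-fold higher (-1.40). Mir1298, in an intron of Htr2c, stood at 606 ± 277 CPM and was 2.05-fold higher (-1.03). Mir195a (516 ± 143 CPM) followed at 1.56-fold and the myeloid Mir223 at 1.45-fold. In the other direction, Mir7b (1143 ± 570 CPM) was 1.99-fold higher in replicate 1 (log2 ratio 1.00) and Mir181b-2 (2139 ± 1037 CPM) 1.95-fold (0.96). Mir138-2 (233 ± 105 CPM) was 1.85-fold higher, Mir138-1 (401 ± 172 CPM) 1.79-fold and Mir182 1.70-fold. Mir181b-2, Mir138-1 and Mir138-2 share runs with another locus and are uncertain. All 10 passed the exact test after Benjamini-Hochberg adjustment, the largest adjusted p being 1.42e-10 for Mir223, and each rests on 1 library per side.

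**Figure D3:**
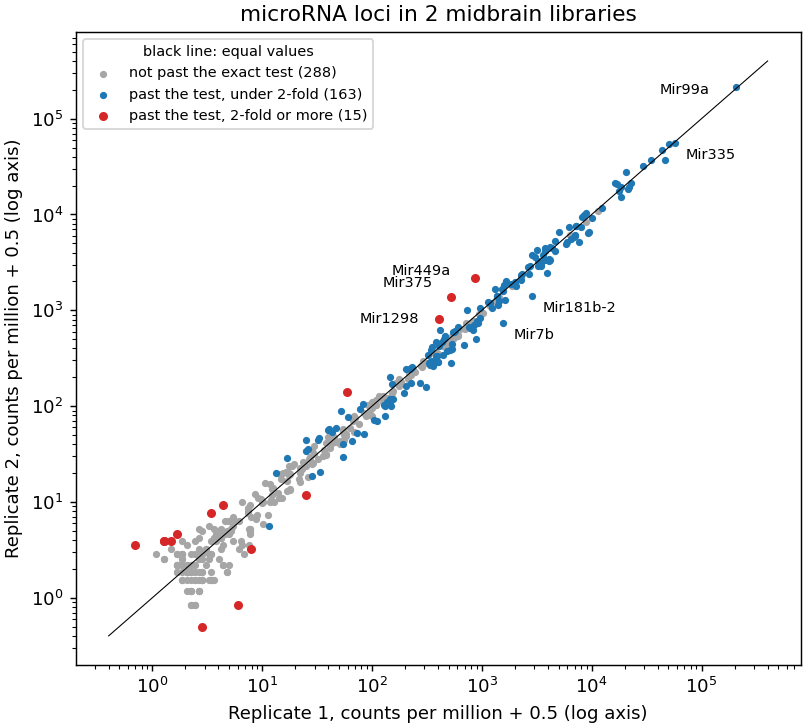
CPM + 0.5 of the 466 tested microRNA loci in replicate 1 (horizontal, log axis) against replicate 2 (vertical, log axis); each point is a locus, coloured by the exact conditional test, and the line marks equal values. Mir375, Mir449a and Mir1298 lie above the line and Mir7b and Mir181b-2 below it.

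Nearly all counts lay on the strand of the annotated locus, 97.7% in replicate 1 and 97.9% in replicate 2 (97.8% ± 0.117, SD, n = 2).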

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

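The tests of the strand of counts, of shared sequence runs and of raw counts at Mir375, Mir449a, Mir1298 and Mir204 were chosen after their results had been seen. The other tests of the replicate difference at Mir375, Mir449a, Mir1298 and Mir204 were written down after that difference was seen and before their own results were.

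Counts on the opposite strand, which enter the results above only through alternative settings and the same-strand share, rose above the limit of a count of 0 at 11 loci with at least 100 such counts in each replicate. Over both replicates these were 58811 at Gm24321, 40286 at Gm25927, 31012 at Gm25252, 18650 at Gm24083, 12366 at Gm25301, 7853 at Gm25750, 6722 at Mir299b, 3838 at Mir497b, 1876 at Mir142b, 379 at Gm25641 and 329 at Gm24111. The microRNA genes that the later annotation places on the other strand there are, in the same order, Mir409, Mirlet7e, Mir376a, Mir191, Mir378a, Mir380, Mir299a, Mir497, Mir142, Mir9-1 and Mirlet7f-1, and none of them has a row. A general loss of strand in the libraries is argued against by the other rows, where 0.00435% of counts were on the opposite strand. Of all opposite-strand counts, 99.8% lay in rows overlapped by such a gene, so these counts may be reads of the gene on the other strand. If so, Mir409 at 7154 ± 899 CPM would rank 29 among the loci and Mirlet7e at 5006 ± 60.3 CPM would rank 39. No biological explanation was tested.

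Multimapping reads were also outside the comparisons, at 3827354 in replicate 1 and 2590773 in replicate 2, or 41.0% and 44.8% of mapped reads. Low counts at loci with near-identical copies, such as those of miR-124, could come from reads left out in this way. List members that share a run of 20 nt had a lower median level than the others (difference of -2.29 log2 units, 87 against 141 loci, permutation p = 0.0023, adjusted p = 0.012 over 5 such tests), which met the criterion set for this explanation. That criterion was met through the Sfmbt2 list: a further check without it gave -1.34 (p = 0.11, adjusted 0.14), and the 3 lists tested singly gave -6.37 for let-7 (exact p = 0.0061, adjusted 0.015), -4.55 for miR-17/92 (exact p = 0.072, adjusted 0.12) and -0.43 for the neuronal list (p = 0.52), all two-sided permutation tests. Counts at identical copies are lowered by the way reads were counted. How far this accounts for the low counts stays open, since the tables do not give multimapping reads by locus, and no biological explanation was tested.

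Mir375, Mir449a, Mir1298 and Mir204 were higher in replicate 2, with a median log2 ratio of replicate 1 to 2 of -1.22. The 4 were grouped after their values were seen and not by fold alone. Mir122 (-1.30) and Mir195a (-0.64), left out of the group, lay further from equal values than Mir204 (-0.54). With total counts only, Mir7b and Mir181b-2 also differed at least 2-fold, in the other direction. Unequal depth alone does not give the raw counts of the 4 loci together. These were 1.22 times as high in the shallower replicate 2 (15710 against 12875, exact interval 1.19 to 1.25), where depth alone gives 0.576, although Mir204 singly had fewer. Mir375, Mir449a and Mir1298 were noticed by their scaled folds. A fold well above the depth ratio of 1.74 implies more raw counts in replicate 2. The raw counts therefore restate the pattern and are no separate test. With replicate 1 thinned the median was -1.25, which by itself could hardly have come out otherwise. Across loci, the ratio showed almost no linear trend with hairpin GC content. Spearman's rho of the ratio with GC content was 0.02 across loci, and the slope over 205 loci was -0.0045 per 10 percentage points. Removing that trend left the median at -1.23. The SD of the ratio over these loci was 0.312284 before and 0.312262 after. Almost nothing was removed, so the median could hardly have moved and the removal decides nothing. Effects of GC content that are not linear stay open. More choroid plexus tissue in replicate 2 is a candidate explanation: held-out loci of the Htr2c intron and the Mir449 and Mir34b/c clusters had a median of -0.90 (7 of 7 tested negative, 4 past the exact test), below all 10000 random lists matched on expression. Of those 7, 5 share a transcript or cluster with Mir1298 or Mir449a and are not independent of the pattern, and the independent ones, Mir34b and Mir34c, gave -0.50 (adjusted exact p = 0.12) and -0.16 (adjusted exact p = 0.0030). Mir375 and Mir122 are no choroid plexus markers. Markers of other cell types were mixed. Endothelial Mir126a (-0.45) and the summed counts of the mural list (-0.34) lay the same way. So did the summed counts of the regional Hox list (-0.25), with Mir10a at -0.36 but Mir615, not past the test, at 0.35. In the leukocyte list Mir223 (-0.54) and Mir146 (-0.55) lay the same way, but Mir155 (0.18) and Mir150 (0.11), neither past the test, did not. The leukocyte list had a median of 0.11, whereas its summed counts gave -0.23, the same way as the pattern. Erythroid Mir451a (0.37) lay the other way, but Mir144 (-0.35) and Mir486 (-0.23) did not. The summed counts of the erythroid list gave 0.039. The summed counts of the epithelial list (0.20) also lay the other way, with Mir182 at 0.76 but Mir203 at -0.17. A wider difference in tissue between the embryo pools stays open and untested.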

How the results depend on the processing

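The alternatives with a required fold, without Mir99a, with multimapping reads, with added opposite-strand counts, and with total counts for the list sums were chosen after seeing the data. Spearman's rho was 0.938 with no filter and 0.993 with at least 100 counts, against 0.983; a different set of loci enters each. Requiring a fold of at least 1.5 left 34 of 178 called loci, by construction. The share of the top 10 was 52.7% with unstranded counts, and 29.7% with multimapping reads in the denominator, against 53.9%; 50 loci held 86.8%. The share in all lists was 73.4% with unstranded counts, 68.3% without Mir99a and 75.4% with opposite-strand counts added, against 75.0%. Lists at or above the 95th percentile fell from 16 to 6 when only loci with at least 10 counts were used. Mir335 turned from -0.05 to 0.016 on the log2 scale with total counts only. Mir181c turned from -0.02 to 0.042 with total counts only and 0.0077 with no filter, where its call ended (adjusted exact p = 0.62). These sign changes follow from the scaling: leaving out the TMM factors (1.023 and 0.977) shifts the ratios of all loci alike, toward replicate 1. Leaving out a replicate gave 482 to 509 loci at 1 CPM, a top-10 share of 53.4% to 54.7%, a list share of 74.9% to 75.1%, 16 to 17 lists at the 95th percentile, and a same-strand share of 97.7% to 97.9%. The coefficient of variation stayed between 0.155 and 0.159, and the number of called loci between 160 and 183 under the planned settings. Counted once per named locus and alternative setting, 381 ratios were the same, 7 lost the call, 13 gained it and 3 reversed. Counted once per list and setting, 10 list percentiles fell below the 95th and 1 rose above it. No paired analysis was possible because the series has 1 group. Depth limits statements on loci under 1.02 CPM in replicate 2.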

Other observations

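Loci of 5 microRNA clusters, chosen after their values were seen, are described here, each within 47408 nt or less of the genome. Values are mean CPM ± SD over n = 2. In the miR-17/92 cluster, which spans 836 nt of chromosome 14, Mir17 stood at 41984 ± 6815 CPM, Mir20a at 16879 ± 2464 CPM, Mir18 at 5991 ± 657 CPM, Mir92-1 at 3167 ± 364 CPM, Mir19a at 83.6 ± 6.97 CPM and Mir19b-1 at 17.3 ± 3.42 CPM. Mir17 was thus 502 times as high as Mir19a, which shares no run of 20 nt with another locus. Mir99a was 728 times as high as its neighbour Mirlet7c-1 (288 ± 4.38 CPM) and 105 times as high as Mir125b-2 (1986 ± 2.72 CPM), both of which do share such runs.

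Within the Mir106b cluster, Mir25 stood at 579 ± 26.0 CPM, a level 35.9 times below that of Mir93. The Mir183 cluster was more even, at 984 ± 67.3 CPM for Mir183, 697 ± 276 CPM for Mir182 and 316 ± 34.4 CPM for Mir96. Yet Mir182 was higher in replicate 1 with a log2 ratio of 0.76, against 0.07 for Mir183 and 0.16 for Mir96. Of the miR-302 cluster, Mir302a, Mir302b, Mir302c and Mir302d were detected, while Mir367 had a mean of 0.170 CPM, under the limit that 3 counts set in either library. Whether processing, stability, ligation in the library or multimapping sets these differences was not tested.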
